A study of Monodelphis domestica with 27 samples.

How the data were processed

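Gene expression was measured by RNA sequencing in 27 libraries from fat of the gray short-tailed opossum (Monodelphis domestica), a marsupial. Per the labels, 3 depots were sampled: anterior subcutaneous, inguinal and interscapular fat. Per the labels, each depot was taken at 6 and at 10 weeks of age from animals of both sexes. The column names of the anterior and inguinal files also carry a number followed by d, read here as days. It is 45 in the 6-week libraries and 70, 71, 72 or 77 in the 10-week ones, so the exact ages may differ from the labels' weeks and within the older group. The interscapular column names carry no such number. The labels' weeks were used throughout. The interscapular column names hold iWAT, the code that the inguinal ones hold, and the depot was also taken from the labels. Per the labels' protocols, RNA was extracted with Qiazol. The same protocol text describes a paired-end preparation from mRNA captured on oligo(dT) beads and a single-end preparation from total RNA with a NUGEN kit, and does not say which libraries had which. The interscapular files name their columns in another way than the anterior and inguinal files and hold fewer counts, so depot and preparation cannot be separated in any comparison of interscapular with another fat. Each preparation, if it followed the depot, held both ages, so the comparisons of age within a depot do not cross it.

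The deposited files hold whole-number counts of reads per gene, not normalized, for 34985 Ensembl gene identifiers in each library. STAR is the only tool named in the submitters' processing notes. Its version, the genome build, the annotation, the counting tool and the strand setting are not given in the sources used here. Reads shared by near-identical or overlapping genes may therefore have been split or dropped in a way that is not known. No column of the files was left unmapped to a sample. The files do not pair the identifiers with gene names, and the RefSeq gene table at hand has an Ensembl identifier in 0 of its 32665 rows, so 0 identifiers were matched to a symbol. For this reason no gene is named, no coordinates are given, and the 37 gene lists fixed in advance could not be tested. The rule fixed for named genes asked for set symbols, for members of those lists, and for the genes with the largest rise and fall in each age comparison and between anterior and inguinal fat, among genes with adjusted p under 0.05, a mean CPM (counts scaled to the effective library size) of at least 1 and groups whose CPM ranges did not overlap (between depots, the same sign in every animal with both). In other comparisons it took the genes with the smallest p in each direction. The first parts named none. In the others the need for a symbol was dropped and up to 2 identifiers per direction were taken; this change was made after the files were seen. Signs per animal used log2 of CPM plus 0.1.

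Total counts per library ran from 10465826 to 14335793 in anterior fat, from 10566674 to 14034861 in inguinal fat and from 3416823 to 6196989 in interscapular fat. The lower depth of the interscapular libraries gives less precision for low-abundance genes. Genes detected were therefore also counted after thinning every library to 3400000 counts. The 48 pairs of libraries within a group were compared by chi-square over genes with at least 20 counts in the pair; the statistic per degree of freedom ran from 11.84 to 105.55, so no pair agreed within sampling noise and each library counted as 1 replicate. Animal numbers in the labels show the libraries of a group to be from separate animals.

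Libraries were grouped by depot and age from the labels. Tests used the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest) on the deposited counts, with TMM factors, the filterByExpr filter (minimum count 10, minimum total 15) and Benjamini-Hochberg adjustment; a gene was called at an adjusted p under 0.05. Standard errors are the absolute log2 fold change divided by the square root of F. The number of genes with an unadjusted p under 0.05 that chance gives is 0.05 of the genes tested. It is an average without a spread, and genes are not independent, so a count above it alone shows no excess. Age was tested within each depot, as 10 against 6 weeks. Depots were compared with the animal as a block, since the labels give anterior and inguinal libraries for 9 animals, interscapular and inguinal for 6, and interscapular and anterior for 5. Deviations from the group means correlated on average at r = 0.32 across genes between the anterior and inguinal libraries of 1 animal, with a minimum of -0.08, and at -0.08 between different animals of 1 age. The means were 0.24 for interscapular and anterior libraries of 1 animal (-0.04 for different animals) and -0.03 for interscapular and inguinal ones (0.01 for different animals), so over all genes no pairing was seen for the last. Over 100 genes that vary between animals, 5 of 5 interscapular libraries were nearest to the anterior and inguinal libraries of their own animal, averaged (4 of 5 over 300 genes); inguinal libraries alone were not tried. The interaction of age and depot was fitted with the animal block for anterior and inguinal fat and without it for the pairs that include interscapular fat. Sex was tested within each depot, as female against male with age as a covariate. Correlations of age effects across genes used log2 CPM with a prior count of 2; their chance level came from 100 permutations of age among animals, made jointly in both depots because the depots share animals. Differences of 1 value per animal were tested by exact permutation.

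The label of 6-week interscapular replicate 1 gives animal 1727, while the column name in its file carries 1729. The label was used, and 1729 was tried as an alternative.

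The fits were tested on simulated data in which 200 genes were changed by known folds, with the means, spreads and library sizes of the real libraries. Of the genes changed 2-fold, 41.8% were called in the anterior age comparison (14785 genes), 37.3% in the inguinal one (13925 genes), 11.9% in the interscapular one (13093 genes), 79.1% between anterior and inguinal fat (14439 genes) and 38.8% in the interaction of those depots with age (15350 genes). Of the genes changed 4-fold, those shares were 72.7%, 87.9%, 74.2%, 90.9% and 75.8%.

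The designs and tests of the fits and of the age effect correlations, and most alternatives, were fixed before the data were examined. The distance between the depots of an animal and the covariances of age effects were not among those designs. The alternatives were DESeq2's size factors, no filter, a stricter filter (1 CPM), the Wald test of DESeq2 1.42.0, leaving out each library, sex as a covariate, the replicate number as a block, and fits with and without the animal block. Added after the data were seen were fits without animals 1848 and 1849, fits without the 2 interscapular libraries with the most genes detected, and animal 1729 in place of 1727.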

Results

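The transcriptomes of 3 fat depots of the opossum were compared at 6 and 10 weeks of age, to describe the expression signature of each depot and how it differs with age. Anterior subcutaneous fat was represented by 5 libraries at 6 weeks and 4 at 10 weeks, inguinal fat by 5 and 5, and interscapular fat by 4 and 4. The libraries came from 12 animals by their labels. Mean depth was 11710000 ± 1100000 counts (SD, n = 9) in anterior, 11980000 ± 1040000 (SD, n = 10) in inguinal and 4740000 ± 1040000 (SD, n = 8) in interscapular fat. Values below are deposited counts scaled to CPM. Genes are given by their identifiers, because the files do not pair them with names.

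The first principal component of log2 CPM held 46.2% of the variance and the second 23.2%. Interscapular libraries lay apart from the other libraries on the first component, which is also the split that a difference of library preparation would follow. Identifier ENSMODG00000038876 took 3.82% ± 0.571 of all counts (SD, n = 8) in interscapular libraries. Its share was 0.0582% ± 0.00969 (SD, n = 9) in anterior and 0.0673% ± 0.0114 (SD, n = 10) in inguinal libraries. Identifier ENSMODG00000010811 took 1.40% ± 0.381 of the counts (SD, n = 9) in anterior, 2.42% ± 0.685 (SD, n = 10) in inguinal and 2.53% ± 0.565 (SD, n = 8) in interscapular libraries. These 2 identifiers, and ENSMODG00000019652 below, were singled out for their abundance after their values were seen.

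**Figure D1:**
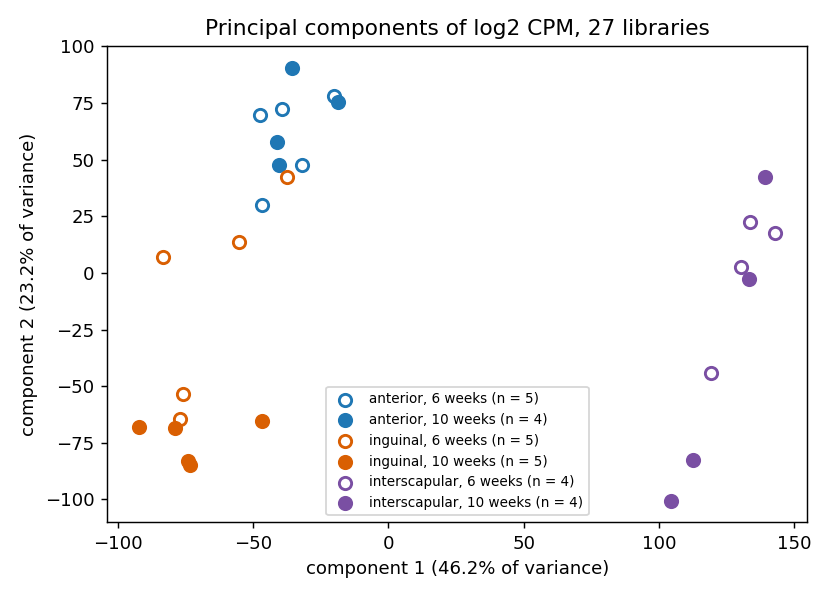
Principal components of log2 CPM over the 27 libraries. The axes are the scores on the first 2 components, with 46.2% and 23.2% of the variance; each point is a library, coloured by depot, open at 6 weeks and filled at 10 weeks, and the 8 interscapular libraries lie apart on the first axis.

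Inguinal fat showed the largest number of genes called between the ages among the 3 depots. Of 13925 genes tested, 1057 were higher and 1155 lower at 10 weeks than at 6 weeks (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). At least 2-fold changes made up 306 of the genes that rose and 635 of those that fell. ENSMODG00000006442 rose from 4.09 ± 2.28 CPM (SD, n = 5) to 260 ± 413 CPM (SD, n = 5), a log2 fold change of 5.97 (SE 1.16, edgeR adjusted p = 0.00674). Its spread at 10 weeks came from replicate 3, at 990.1 CPM; without it the 10-week mean was 77.4 ± 74.8 CPM (SD, n = 4). ENSMODG00000039106 rose from 0.128 ± 0.0822 to 3.63 ± 2.66 CPM (SD, n = 5 each), a log2 fold change of 4.64 (SE 0.74). ENSMODG00000051206 was lower at 10 weeks, at 0.722 ± 0.837 CPM against 32.4 ± 18 CPM (SD, n = 5 each), a log2 fold change of -5.45 (SE 0.85, edgeR adjusted p = 0.00228). ENSMODG00000010887 was at 0.192 ± 0.253 CPM at 10 weeks and at 5.89 ± 4.74 CPM at 6 weeks (SD, n = 5 each), and without 10-week replicate 2 the 10-week mean was 0.0861 CPM. Each of these 4 genes was called in all 10 fits without 1 library. The 2 ages did not overlap in CPM for 12.6% of the tested genes, where chance gives 0.79%. The count of called genes was 1327 without 6-week replicate 4, 1261 without 10-week replicate 4, and 1036 without 6-week replicates 4 and 5 together, which were left out after their values were seen. Of 1051 genes that rose and were also tested between anterior and inguinal fat, 699 were higher in inguinal and 26 in anterior fat. Independent lists would share 344 and 270. Of 1151 that fell, 502 were higher in anterior and 150 in inguinal fat, against 296 and 377. Both comparisons use the inguinal libraries, so these lists are not independent. The overlaps do not separate age from the position of 6-week libraries between the depots.

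In anterior subcutaneous fat 19 genes were higher and 30 lower at 10 weeks, among 14785 tested. ENSMODG00000039586 rose from 25.3 ± 9.64 CPM (SD, n = 5) to 252 ± 216 CPM (SD, n = 4), a log2 fold change of 3.30 (SE 0.53, edgeR adjusted p = 0.044). Its 10-week mean came largely from replicate 2, at 556.9 CPM; without it the mean was 150 ± 86.9 CPM (SD, n = 3) and the log2 fold change 2.56 (SE 0.38, edgeR adjusted p = 0.089). ENSMODG00000000172 rose from 0.273 ± 0.130 (SD, n = 5) to 4.92 ± 3.52 CPM (SD, n = 4). ENSMODG00000007462 fell from 93.4 ± 57.9 (SD, n = 5) to 3.92 ± 3.60 CPM (SD, n = 4), a log2 fold change of -4.57 (SE 0.69, edgeR adjusted p = 0.044), with a 10-week mean of 2.14 CPM without replicate 3. ENSMODG00000009414 fell from 13 ± 8.35 (SD, n = 5) to 0.807 ± 0.582 CPM (SD, n = 4). These 4 genes were chosen for ages that do not overlap in CPM, so their direction was bound to hold in the 9 fits without 1 library. In those fits ENSMODG00000000172 was called in 3 and the others in 2. The count of called genes rests on single libraries and on the tool. It was 3, 3, 3, 4, 4, 4 and 6 without 6-week replicate 5, 10-week replicates 1 and 2, 6-week replicates 2, 3 and 4, and 10-week replicate 4, in that order, 155 without 6-week replicate 1, and 390 without 10-week replicate 3. DESeq2 called 1133 genes; with sex as a covariate edgeR called 19 higher and 5 lower, which held 11 of the 49 genes, and without animals 1848 and 1849 it called 179, which held 34 of the 49. An unadjusted p under 0.05 was reached by 2882 genes, where chance gives 739 on average, with a spread that was not estimated.

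In interscapular fat 2 genes were higher and 7 lower at 10 weeks, among 13093 tested. ENSMODG00000018492 rose from 9.32 ± 4.07 to 56.2 ± 14.5 CPM (SD, n = 4 each), a log2 fold change of 2.57 (SE 0.33, edgeR adjusted p = 0.0481). ENSMODG00000044265 rose from 49.6 ± 4.95 to 112 ± 15 CPM (SD, n = 4 each). ENSMODG00000012713 fell from 32.2 ± 6.08 to 3.91 ± 1.43 CPM (SD, n = 4 each), a log2 fold change of -3.08 (SE 0.27, edgeR adjusted p = 0.016). ENSMODG00000001014 fell from 63.6 ± 8.54 to 8.07 ± 3.04 CPM (SD, n = 4 each). These 4 genes were chosen for ages that do not overlap in CPM, so their direction was bound to hold in the 8 fits without 1 library. In those fits each that rose was called in 1 and each that fell in 4. The count was 0 without 6-week replicate 1, 2 or 3, 1 without 10-week replicate 1, 3 without 10-week replicate 3 or 4, 5 without 6-week replicate 4, and 21 without 10-week replicate 2. It was 3 with sex as a covariate, 31 without the filter, 14 under the stricter filter and 320 by DESeq2. It was 16 without the 2 libraries with the most genes detected. An unadjusted p under 0.05 was reached by 1567 genes, where chance gives 655 on average, with a spread that was not estimated.

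**Figure D2:**
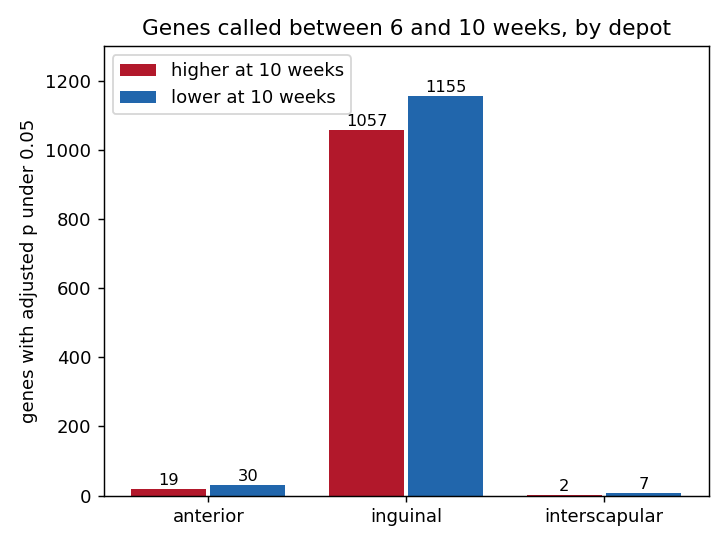
Number of genes called between 6 and 10 weeks in each depot. Bars start at 0 and give the genes with an adjusted p under 0.05 that were higher (red) or lower (blue) at 10 weeks: 19 and 30 in anterior, 1057 and 1155 in inguinal, 2 and 7 in interscapular fat.

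The direction of the age difference was compared between depots. Of the inguinal calls that were tested elsewhere, 95.8% (1972 of 2058) had the same direction in interscapular and 81.7% (1795 of 2196) in anterior fat. The 9 interscapular calls were all called in inguinal fat in the same direction. Of the anterior calls, 11 that rose and 21 that fell were called in inguinal fat in the same direction, and 0 in the opposite one; independent lists would share 1.37 and 2.43, a value that leaves out the animals common to both depots. ENSMODG00000019652 rose in share of counts in each depot: from 0.584% ± 0.229 (SD, n = 5) to 1.715% ± 0.519 (SD, n = 4) in anterior, from 1.01% ± 0.219 to 3.10% ± 0.545 (SD, n = 5 each) in inguinal and from 0.565% ± 0.166 to 1.455% ± 0.249 (SD, n = 4 each) in interscapular fat, and the ranges of the 2 ages did not overlap in any of the 3 depots.

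Since the depots share animals, part of this agreement may arise without an effect of age. Regrouped animals still differ in age, so the permuted means below may hold part of the age difference. They do not measure how much agreement shared animals give. Its chance level was taken, after the data had been seen, from 100 joint permutations of age among animals, with genes ranked by a pooled t statistic on log2 CPM. Of the 2212 highest-ranked inguinal genes, 97.3% of those tested in interscapular fat had the same direction there, against a permuted mean of 62.5% and a highest of 95.9% (one-sided permutation p = 0.0099, the smallest possible, adjusted p = 0.05 over 5 such measures). In anterior fat 84.4% had the same direction, against a permuted mean of 79.3% (one-sided permutation p = 0.39), so this share was not shown to exceed what regrouped animals give. Of the 49 highest-ranked anterior genes, 32 were among those inguinal genes in the same direction, against a permuted mean of 18.9 (one-sided permutation p = 0.04, adjusted p = 0.067). With animal 1729 in place of 1727 the permutations were redrawn, and that one-sided permutation p was 0.03 (adjusted p = 0.038). No anterior or inguinal library is labelled 1727, and in the 2 sets 3 and 2 of 100 permutations were as large. Whether this overlap passes the threshold is therefore not settled by 100 permutations. The adjusted p of the interscapular share was 0.025 with animal 1729. Across 12417 genes, which are not independent replicates, the age effects of interscapular and inguinal fat correlated at r = 0.828. The mean over 100 joint permutations of age among animals was 0.184 and the highest 0.776, so the one-sided permutation p was 0.0099, the smallest these permutations can give (adjusted p = 0.03 over the 3 pairs). For anterior and inguinal fat r was 0.598, with a permuted mean of 0.373 and a one-sided permutation p of 0.17, and for interscapular and anterior fat it was 0.558, with a permuted mean of 0.264 and a p of 0.16. Leaving out 1 library at a time gave r of 0.725 to 0.839 for interscapular and inguinal and 0.353 to 0.733 for interscapular and anterior fat. For anterior and inguinal fat r rose to at most 0.677 and did not fall by as much as 1.5 times. That of interscapular and anterior fat fell by over 1.5 times without interscapular 10-week replicate 2 (0.353) or replicate 1 (0.369). The correlation therefore passed the threshold for 1 of these 3 pairs, interscapular and inguinal fat. Mean scores on the axis from anterior to inguinal fat described below were higher at 10 weeks in both depots of that pair. They went from 0.77 to 1.25 in inguinal and from 0.14 to 0.38 in interscapular fat, and neither difference passed the threshold. Axis position was not removed from the age effects, so its part in this agreement was not tested. The covariances of the age effects were 0.228, 0.277 and 0.147 for anterior with inguinal, interscapular with inguinal and interscapular with anterior fat, against permuted means of 0.052, 0.027 and 0.038 (one-sided permutation p = 0.02, 0.0099 and 0.04, adjusted p = 0.03, 0.03 and 0.04). With animal 1729 in place of 1727, and the permutations redrawn, the one-sided permutation p of the last pair was 0.05 after rounding. That lies at the edge of the threshold, so 100 permutations do not settle the call on this pair. With each animal used in 1 depot alone, r over 50 draws, which overlap in animals, was 0.431 ± 0.173, 0.631 ± 0.104 and 0.38 ± 0.201 (mean ± SD over draws). The draws ran from 0.099 to 0.717, from 0.313 to 0.793 and from -0.017 to 0.692, so those of the last pair reached below 0.

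**Figure D3:**
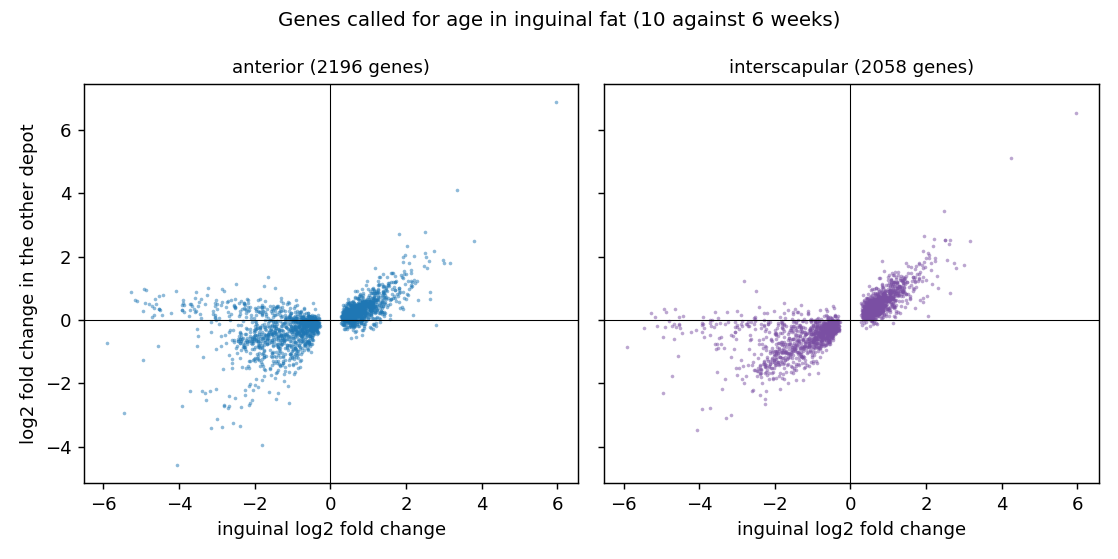
Age effects of the genes called in inguinal fat, in the other depots. The x axis is the inguinal log2 fold change (10 against 6 weeks), the y axis that of anterior (left, 2196 genes) or interscapular fat (right, 2058 genes), each point is a gene, and 81.7% and 95.8% of the points have the same sign on both axes.

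Anterior and inguinal fat differed in most of the genes tested. With the animal as a block, 4042 genes were higher in anterior and 4525 higher in inguinal fat, of 14439 tested. At least 2-fold differences made up 1420 of those higher in anterior and 590 of those higher in inguinal fat. ENSMODG00000002120 was at 365 ± 156 CPM in anterior (SD, n = 9) and 47.1 ± 77.1 CPM in inguinal fat (SD, n = 10), a log2 fold change of 5.62 (SE 1.30, edgeR adjusted p = 0.00345). It was higher in anterior fat in 9 of 9 animals, which the rule for its choice required. Its inguinal mean came from 6-week replicates 2, 4 and 5, at 128.6, 111.4 and 215.9 CPM, while the other inguinal libraries lay between 0.849 and 5.71 CPM; the fold change is fitted within animals and is not the ratio of these means. Without 6-week replicate 5 the inguinal mean was 28.3 CPM. ENSMODG00000020324 was at 264 ± 112 CPM (SD, n = 9) and 30.8 ± 51.8 CPM (SD, n = 10), with 73, 69.2 and 153 CPM in those 3 inguinal libraries and an inguinal mean of 17.2 CPM without 6-week replicate 5. ENSMODG00000000463 was at 3.82 ± 3.66 CPM in anterior (SD, n = 9) and 87.8 ± 36.8 CPM in inguinal fat (SD, n = 10), a log2 fold change of -4.83 (SE 0.59, edgeR adjusted p = 0.000154). ENSMODG00000000453 was at 0.231 ± 0.237 (SD, n = 9) and 3.73 ± 1.54 CPM (SD, n = 10). The 6-week libraries alone gave 5350 genes and the 10-week libraries alone 7390.

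The distance between anterior and inguinal fat of the same animal was larger at 10 weeks. The root mean square log2 difference over 15225 genes was 0.821 ± 0.247 at 6 weeks (SD, n = 5) and 1.32 ± 0.102 at 10 weeks (SD, n = 4; exact permutation test, two-sided p = 0.0159). The largest 6-week value was 1.155 and the smallest 10-week value 1.221. The lowest values, 0.558 and 0.602, were those of animals 1849 and 1848, and the next, 0.844, that of animal 1764. On the axis from anterior to inguinal fat described below, their inguinal libraries had the lowest scores of that depot (0.20, 0.52 and 0.64). Anterior-like tissue in an inguinal sample would shorten this distance without an effect of age. Such a mixture is not excluded below, so it cannot be told apart here from an age difference.

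**Figure D4:**
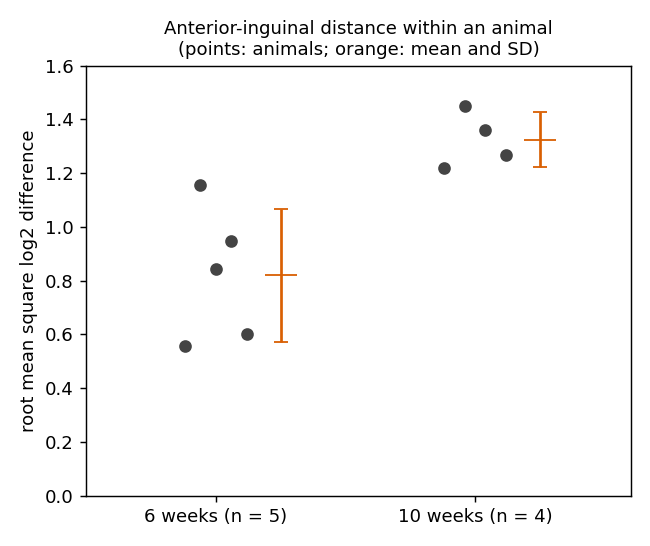
Distance between the anterior and inguinal libraries of each animal at 6 and 10 weeks. The y axis is the root mean square difference in log2 CPM, each point is an animal, and the orange marks give the mean and SD, 0.821 ± 0.247 and 1.32 ± 0.102.

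Whether the age difference itself differed between depots was tested as an interaction. Between anterior and inguinal fat 611 of 15350 genes were called, and this count rests on single animals. An unadjusted p under 0.05 was reached by 3940 genes, where chance gives 768 on average. In 324 of the called genes the anterior change lay above the inguinal one, with a median log2 fold change of 0.11 in anterior and -1.44 in inguinal fat. In 287 it lay below, with medians of -0.18 and 0.50. ENSMODG00000005140 was at 23.5 ± 3.24 and 24.0 ± 4.05 CPM in anterior fat at 6 (SD, n = 5) and 10 weeks (SD, n = 4), and at 16.7 ± 2.26 and 5.13 ± 0.837 CPM in inguinal fat (SD, n = 5 each; interaction log2 1.76, SE 0.13, edgeR adjusted p = 0.00102). ENSMODG00000008620 was at 32.4 ± 6.55 (SD, n = 5) and 30 ± 8.05 CPM (SD, n = 4) in anterior and 31.1 ± 5.22 and 60.8 ± 12.8 CPM (SD, n = 5 each) in inguinal fat (interaction log2 -1, SE 0.13). Without animals 1848 and 1849 the count was 1. In that fit all 611 genes kept their direction and had an unadjusted p under 0.05. Their median absolute log2 difference was 0.93 (SD over genes 0.93, median SE 0.23), beside 0.99 (SD over genes 1.08, median SE 0.2) with all animals. The fold was smaller for 377 of them. The 611 genes were chosen in a fit that holds the same remaining animals, so this is no independent test of them. Over all 15399 genes of that fit 2280 had an unadjusted p under 0.05, where chance gives 770. Under the animal block, leaving out 1 library takes its animal out of the test, so the 2 libraries of an animal do not give separate refits. Leaving out a single library moved the count of called genes over 1.5 times in 18 of 19 refits. It was between 1 and 15 without any of anterior 6-week replicates 1, 3, 4 and 5, anterior 10-week replicates 1, 2 and 4, inguinal 6-week replicates 2, 3, 4 and 5, and inguinal 10-week replicates 1, 2 and 5. It was 1711, 1545, 1716 and 1563 without anterior 6-week replicate 2, anterior 10-week replicate 3, inguinal 6-week replicate 1 and inguinal 10-week replicate 3. It was 1659 by DESeq2. Without the animal block it was 403, of which 91.6% lay above, against 53% with the block and 65.3% without the filter. In the refits that called between 1 and 15 genes, 2992 to 3701 genes had an unadjusted p under 0.05.

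No interaction was called between interscapular and inguinal or between interscapular and anterior fat. The edgeR counts were 0 and 0, DESeq2 called 3 and 1, and 740 and 713 genes had an unadjusted p under 0.05, where chance gives 782 and 791. On simulated data these fits called 42.4% and 59.1% of genes changed 4-fold and 6% and 10.4% of genes changed 2-fold, so most differences of the smaller size would have been missed.

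Interscapular fat was compared with the other depots within animals, as values of libraries that may also differ in preparation. Against inguinal fat 4952 genes were higher and 5367 lower in interscapular libraries, of 14424. Against anterior fat 4640 were higher and 5188 lower, of 14681. ENSMODG00000006089 was at 139 ± 31.9 CPM in interscapular (SD, n = 8) and 5.38 ± 7.26 CPM in inguinal libraries (SD, n = 10), or 3.42 CPM without 10-week replicate 5. ENSMODG00000050148 was at 152 ± 66.9 CPM in interscapular (SD, n = 8) and 0.266 ± 0.147 CPM in anterior libraries (SD, n = 9). ENSMODG00000045008 was low in interscapular libraries in both comparisons, at 0.898 ± 0.469 CPM (SD, n = 8) beside 116 ± 34.5 CPM in inguinal (SD, n = 10).

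Few genes were called between the sexes. ENSMODG00000005735 was higher in females in each depot, at 74.5 ± 24.2 (SD, n = 5) against 15.7 ± 4.40 CPM (SD, n = 4) in anterior, 69.9 ± 28.1 against 15 ± 4.52 CPM (SD, n = 5 each) in inguinal and 110 ± 31 against 32.4 ± 8.32 CPM (SD, n = 4 each) in interscapular fat (edgeR adjusted p = 0.00676, 0.00126 and 0.0112). ENSMODG00000015320 was called in anterior and inguinal fat, at 18.3 ± 1.73 (SD, n = 5) against 3.47 ± 1.30 CPM (SD, n = 4) and 17.7 ± 1.67 against 4.25 ± 1.23 CPM (SD, n = 5 each); in interscapular fat it was at 14.2 ± 0.963 against 3.63 ± 1.48 CPM (SD, n = 4 each; edgeR adjusted p = 0.429). For both genes 0 of 27 libraries lay on the side of the other sex. In total 7 genes were called in anterior, 2 in inguinal and 3 in interscapular fat. An unadjusted p under 0.05 was reached by 1345, 897 and 457 genes, where chance gives 739, 696 and 655, and on simulated data 37.3%, 38.8% and 6% of genes changed 2-fold were called. DESeq2 called 187, 145 and 12. Without the filter the interscapular count was 579. The anterior count was 18 without 6-week replicate 1, 0 without 6-week replicate 3, 1 without 6-week replicate 4 or 10-week replicate 1 or 3, 2 without 6-week replicate 2 and 3 without 6-week replicate 5. The inguinal count was 1 without 10-week replicate 4. The interscapular count was 0 without 6-week replicate 1 or 2, and 1 without 6-week replicate 3 or 4 or 10-week replicate 1, 2 or 3.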

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

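Of the tests in this part, those on the fits without animals 1848 and 1849 were chosen after the data had been seen. In 122 groups of 4 to 10 libraries, 9 had a highest or lowest library far from the others, where chance gives about 1 in 20.

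A pair of results marked the age difference as unequal between anterior and inguinal fat. Both rest on the anterior-inguinal differences within the same animals, so they are not independent of each other. In the interaction of age and depot 611 genes were called. The distance between the 2 depots of an animal differed between the ages (exact permutation p = 0.0159), a test not among the designs fixed in advance. Anterior-like tissue in the 6-week inguinal samples, weighed below, would by itself lower the 6-week distances. Along with these results, 2212 genes were called for age in inguinal and 49 in anterior fat. Of the 100 splits drawn of the inguinal libraries, 1 gave as many genes, the real one, a share under 0.05, and the highest other gave 1. Of the 100 drawn of the anterior libraries, 4 gave as many, the real one included, also a share under 0.05, yet the highest other gave 1129 genes. That split exchanged 6-week replicate 1 with 10-week replicate 3, which points to a structure of the anterior libraries other than age. Of 100 regroupings of age among the animals, 2 gave as many interaction genes, the real one included, and the highest other gave 1377, more than the real count. The shares of splits here and below were not adjusted for the number of comparisons, so a share under 0.05 does not by itself exclude chance.

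The gap between 2212 and 49 genes was weighed against 3 technical explanations. The extra inguinal library does not account for it, since without its animal 1261 genes were called in inguinal fat. Unequal sexes between the ages do not, since with sex as a covariate 2275 genes were called in inguinal and 24 in anterior fat. The 2 inguinal 6-week libraries nearest the anterior ones do not alone account for all of it. Without both, 1036 were called, beside 179 in anterior fat without the same animals. Inguinal 6-week replicate 2, at 0.64 on the axis described below, stayed in that fit, so anterior-like 6-week libraries as a group are not excluded. In those fits 3703 inguinal and 3479 anterior genes had an unadjusted p under 0.05, beside 4387 and 2882 with all animals. By DESeq2 the counts of called genes with all animals were 3186 and 1133. A larger age difference in inguinal fat may be a biological hypothesis that stays open. The test of the difference itself fell from 611 genes to 1 without animals 1848 and 1849, and to between 1 and 15 without any of 14 single libraries. In those 14 refits 2992 to 3701 genes had an unadjusted p under 0.05, beside 3940 with all animals. Under the animal block, leaving out 1 library takes its animal out of the test, so the 14 refits pair up by animal. Some of these libraries are of other animals, so the loss is not particular to animals 1848 and 1849. The 611 genes all kept their direction without animals 1848 and 1849, and 377 had a smaller fold. Their median absolute log2 difference was 0.93 (SD over genes 0.93), beside 0.99 (SD over genes 1.08). They were chosen for the effect in a fit that holds the same remaining animals, so this cannot show that the effect persists. The median SE rose from 0.2 to 0.23 with fewer animals, and the smallest adjusted p was 0.0417.

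Six-week inguinal libraries were spread along the axis from anterior to inguinal fat. The axis was built from the paired differences of the other animals, with 0 at the mean of their anterior libraries and 1 at the mean difference. Inguinal 6-week replicates 1 to 5 scored 1.20, 0.64, 1.28, 0.52 and 0.20, and the 10-week ones ran from 1.09 to 1.34. Anterior-like tissue mixed into replicates 4 and 5 was tested by the share that 2 sets of genes give. The references were the 6-week animals 1729, 1764 and 1766. The inguinal library of animal 1764 is replicate 2, which itself scored 0.64, so it does not stand for unmixed inguinal fat. In replicate 5 the shares were 94.6% ± 43.5 from genes higher in anterior and 59.5% ± 20.2 from genes higher in inguinal fat (SD, n = 3 reference animals), a mean difference of 35.1 percentage points. The bound set beforehand, 2 SD of the difference, came to 47.3 points there, and 1 reference gave a share of 144.5%, so the test is too coarse for replicate 5; this limit on its use was set after the shares were seen. In replicate 4 the shares were 33.5% ± 26.8 and 34.7% ± 21.4, a difference of -1.2 points within the bound of 13.6, as a mixture would give. They were 8.1% and 17.1% against animal 1764 and 61.6% and 58.5% against animal 1766, so their size depends on the reference. For both libraries together a mixture cannot be told apart from another state of the tissue, because replicate 5 and the intermediate reference leave it open. A state of the animal common to its depots was also put forward, after the scores had been seen. The anterior scores of the same animals, in the same order, were 0.04, -0.04, 0.39, 0.16 and -0.15. The animal lowest in inguinal fat was also lowest in anterior fat, and the highest was also highest, the direction such a state would give. In the 10-week animals 1732, 1731, 1743 and 1846 the inguinal scores were 1.27, 1.34, 1.27 and 1.09. Their anterior scores were 0.08, -0.28, 0.17 and -0.19, so there the highest inguinal score went with the lowest anterior one. No correlation across samples is given over as few as 5 animals at 6 weeks, so a state common to the depots stays open.

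The other libraries far from their group are given as values. Anterior 6-week replicate 1 had 14335793 counts, where the others of its group had 10465826 to 11509460. Interscapular 6-week replicate 4 had 23396 genes detected at equal depth, where the others had 18493 to 18752. Inguinal 10-week replicate 5 scored 1.09 on the axis, where the others scored 1.27 to 1.34. ENSMODG00000006442 was at 990.1 CPM in inguinal 10-week replicate 3 and at 19.9 to 177 CPM in the others. ENSMODG00000044265 was at 57.0 CPM in interscapular 6-week replicate 3 and at 46.1 to 47.8 CPM in the others. ENSMODG00000020324 was at 153 CPM in inguinal 6-week replicate 5 and at 0.377 to 73.0 CPM in the other inguinal libraries. ENSMODG00000008620 was at 44.0 CPM in anterior 6-week replicate 4 and at 28.2 to 30.6 CPM in the others. ENSMODG00000000218 was at 11.1 CPM in anterior 10-week replicate 2 and at 25 to 27.3 CPM in the others. ENSMODG00000041375, high in female interscapular libraries, was at 0.522 CPM in the male 6-week replicate 4 and had no counts in the other males of that depot.

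The remaining counts were set beside other splits of their libraries. Between anterior and inguinal fat 1 of 100 exchanges of depot within animals gave as many as 8567 genes, the real one, and the highest other gave 0. Between interscapular and inguinal fat 1 of 32 did, with 10319 and 0. Both shares were under 0.05 without adjustment. Between interscapular and anterior fat the 16 exchanges are too few for a share under 0.05; the real count was 9828 and the highest other 0. In interscapular fat 2 of 35 splits by age gave at least 9 genes and the highest other gave 159, so chance is not excluded, and a split with that many genes points to another structure of these libraries. For the interactions with interscapular fat all 100 of the 100 regroupings reached the real count of 0, and the highest others gave 0 with inguinal and 590 with anterior fat. For sex, 2 of 40 splits of the anterior libraries gave at least 7 genes (highest other 266), which does not exclude chance. Of 100 splits of the inguinal libraries 2 gave 2 genes, the real one included, and the highest other also gave 2. That share is under 0.05 without adjustment and does not by itself exclude chance. The 18 splits of the interscapular libraries are too few for a share under 0.05; the real count was 3 and the highest other 1.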

How the results depend on the processing

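Alternatives with animals 1848 and 1849 left out, with 2 interscapular libraries left out together, and with animal 1729 in place of 1727 were chosen after the data had been seen. Of 72 alternatives that kept single libraries in, 51 left the count of genes within 1.5 times its value and 21 did not. The tests of the gene lists were not run, because no identifier could be matched to a symbol. The cause of the changes below was not tested. By DESeq2 the age counts were 1133 in anterior and 320 in interscapular fat, the interaction of anterior and inguinal fat had 1659 genes, the others 3 (inguinal) and 1 (anterior), and the sex counts were 187, 145 and 12 in anterior, inguinal and interscapular fat. Sex as a covariate gave 24 age genes in anterior and 3 in interscapular fat. Without the filter interscapular counts were 31 for age and 579 for sex, and under the stricter filter 14 for age. Without animals 1848 and 1849 the age counts were 179 in anterior and 1036 in inguinal fat and the interaction 1; without the 2 interscapular libraries the age count was 16. Without the animal block the interaction was 403. At 6 weeks alone 5350 genes differed between anterior and inguinal fat. For anterior with inguinal, interscapular with inguinal and interscapular with anterior fat, disjoint animals gave r of 0.431, 0.631 and 0.38 and Spearman's coefficient was 0.426, 0.725 and 0.437; with animal 1729, disjoint animals gave 0.644 and 0.33 for the last 2 pairs.

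Replicate numbers do not pair animals between ages: deviations of same-numbered libraries correlated at -0.3 to 0.26 in anterior, -0.09 to 0.26 in inguinal and -0.22 to 0.56 in interscapular fat. With the replicate block the age counts were 206 in anterior, 2193 in inguinal and 1 in interscapular fat. With it within age in place of the animal, the depot counts were 7638, 11000 and 10687.

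Of 162 refits without 1 library, 52 moved a count by over 1.5 times. The ranges were 3 to 390 for age in anterior, 1261 to 2281 in inguinal and 0 to 21 in interscapular fat, 7662 to 8551 for anterior against inguinal, 9406 to 10362 for interscapular against inguinal, 8457 to 9924 for interscapular against anterior, 1 to 1716 for the interaction of anterior and inguinal fat, 0 to 0 for both others, and 0 to 18, 1 to 2 and 0 to 2 for sex in anterior, inguinal and interscapular fat. At least 1230 inguinal age genes and 7609 anterior-inguinal genes were called in the same direction in each refit. In interscapular fat, with fewer libraries and counts, 11.9% of genes simulated with a 2-fold age change were called; which of these limits it was not tested.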

Other observations

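The tests of the shared direction, the axis scores and the animal match in this part were chosen after the data had been seen. Across the 12382 genes tested for age in all 3 depots, 540 had an unadjusted p under 0.05 in each depot. All 540 had the same direction in the 3 depots, 240 higher and 300 lower at 10 weeks. Over all 12382 genes 52.9% had the same direction in the 3 depots. The depots share animals, so these are not 3 independent observations. By the pooled t statistic, 575 genes ranked at the top of all 3 depots in the same direction, against a mean of 164.5 and a highest of 602 over 100 joint permutations of age (one-sided permutation p = 0.02, adjusted p = 0.05). For all genes the share was 53.6% against a permuted mean of 40% (one-sided permutation p = 0.059, adjusted p = 0.074). With animal 1729 in place of 1727 in the permutations, the p of the share was 0.03 (adjusted p = 0.038) and that of the 575 genes 0.0099, the smallest these permutations can give (adjusted p = 0.025). The permutations were redrawn for animal 1729, and for the share 5 and 2 of 100 were as large. The animal number and the redrawing cannot be told apart as the source of this move, so the call on the share is not settled.

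A pair of identifiers detected mainly in females were far more abundant in interscapular libraries. ENSMODG00000041375 was at 54.0 ± 14.6 CPM in female interscapular libraries (SD, n = 4), beside 1.32 ± 1.82 CPM in female anterior (SD, n = 5) and 0.875 ± 1.08 CPM in female inguinal libraries (SD, n = 5). ENSMODG00000044298 was at 8.66 ± 3.01, 0.996 ± 0.288 and 0.663 ± 0.296 CPM. In males neither had counts in anterior or inguinal libraries. Whether this follows the depot or the library preparation was not tested.

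Scores on the axis from anterior to inguinal fat were also compared between the ages. In inguinal fat they were 0.77 ± 0.46 at 6 weeks and 1.25 ± 0.10 at 10 weeks (SD, n = 5 each; exact permutation test, two-sided p = 0.0714, adjusted p = 0.214 over the 3 depots). In anterior fat they were 0.08 ± 0.21 (SD, n = 5) and -0.06 ± 0.21 (SD, n = 4; exact p = 0.381). In interscapular fat they were 0.14 ± 0.28 and 0.38 ± 0.61 (SD, n = 4 each; exact p = 0.486), and 10-week replicates 3 and 4 stood at 0.81 and 0.95. None passed the threshold.

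The interscapular library labelled animal 1727 may come from animal 1729, the number in its column name. Genes that vary between animals were chosen from the anterior and inguinal libraries alone, and age and sex were removed from each gene. Over 100 such genes, which are not independent replicates, the library correlated with animal 1729 at r = 0.66. The 5 interscapular libraries whose animals also gave anterior and inguinal libraries each matched their own animal best, at r = 0.26 to 0.79. Shared age and sex alone are argued against, since the highest of the other 66 correlations of an interscapular library with another animal was 0.5, at either age, and 0.29 within an age. The 0.5 lies above the lowest own-animal value, so 1 such correlation alone does not identify an animal. With 30 genes the match, the own-animal range and the highest other were 0.77, 0.52 to 0.81 and 0.58, and with 300 genes 0.51, 0.03 to 0.72 and 0.44, where 4 of the 5 libraries matched their own animal best. The 0.58 was that of the library labelled animal 1730, which also matched animal 1729 best with 30 genes. Animal 1730 gave no anterior or inguinal library, so it had no own match to find. With 100 and 300 genes its r with animal 1729 was 0.22 and 0.07, and other animals matched it better. With age and sex left in, animal 1729 was its best match at 0.63, 0.52 and 0.54 with 30, 100 and 300 genes, where the library labelled 1727 had 0.86, 0.8 and 0.74. A close relative of animal 1729 was not tested and stays open. With animal 1729 as the block, 10899 genes differed between interscapular and inguinal fat, beside 10319.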
